A study of Homo sapiens with 6 samples.

How the data were processed

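The samples were subcutaneous xenografts of U87-EV, a line derived from the established human glioblastoma line U87, grown in BALB/c SCID mice. Per the labels' protocols, each group began with 5 mice, tumours were kept in an RNA preservative, and 10 µg of total RNA per sample was amplified, labelled with biotin and hybridised. The arrays were of the Mouse430_2 type. The authors deposited 1 log2 value per probe set and array, made with GCOS 1.1.1.052 and GCRMA, per the submitters' processing notes. GCRMA corrects the background of each probe with a model of its sequence, and normalizes and summarises probes into probe sets. Dim probe sets lay at floors that differed between them. Some, such as 4.72 for Gpihbp1 and 5.22 for Flt1, were above the mean of 4 used below as a filter. The version of GCRMA and any centring are not given in the sources used here. The lowest value was 2.32 on the log2 scale, and the medians of the 6 arrays lay between 2.51 and 2.63. Because such values are relative within each array, a large class of transcripts in some samples lowers the values of the rest. Raw scanner files were not used here.

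Gene symbols came from the platform annotation. Of the probe sets other than the 64 controls, 34945 had 1 symbol, 932 had several and 9160 had none. No gene was named from a probe set with several symbols, and symbols can be old. No mouse genome was used here, so no coordinates are given.

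Control probe sets were left out, and the 14594 probe sets with a mean log2 value of at least 4 over all 6 arrays were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with a 2-group design and Benjamini-Hochberg adjustment at 0.05. Each of 8438 genes was represented by its probe set with the highest mean. Of 29 gene lists fixed in advance, 25 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01, two-sided, adjusted over the lists, and again with a correlation estimated from the data. The estimated correlation rests on 6 arrays. Beside camera, the limma rotation test fry asked whether each list moved on its own, with its p left unadjusted. Figures were drawn with matplotlib 3.10.9.

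The groups, lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule takes 10 genes per direction with the largest change past the threshold and no overlap of groups, or else the lowest unadjusted p without overlap, the up to 4 members with the largest change in each list, and 13 genes named whatever their values (Kdr, Flt1, Pecam1, Cdh5, Esm1, Dll4, Angpt2, Vegfa, Rgs5, Pdgfrb, Col4a1, Cd68 and S100a8). It gave 130 genes, and the text gives examples from them. They entered the alternative limma fits, 87 of them with the filter at 6, but not the plain test or the other choices of probe set. Chosen after the data had been seen were the comparison without control replicates 1 and 2, the 7 lists of other cell types, the range of 0.02 log2 units that marks a group at its floor, and a limit of 1e-06 below which a difference counted as 0 when signs were compared. Against 1 control array, that array was assumed to vary like the treated ones. Calls in that comparison rest on 1 control sample and not on replication.

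Alternatives were no filter and a filter at 6, quantile normalization, a shift of each array to the same median, eBayes with trend and robust settings, array weights, the replicate number as a block, a plain two-sample test with equal variances, other thresholds, other choices of probe set per gene, and leaving out each array in turn. No arrays held identical values: over all probe sets the correlation between arrays, which is across probe sets and not across samples, was 0.932 to 0.992. The method was tested on simulated data of the 14594 probe sets. With the spread of both groups it recovered 4.5% of probe sets changed by 1 log2 unit, 76.1% by 2 and 93.9% by 4, with 11 false calls. With the smaller spread among treated arrays it recovered 65.7%, 89.6% and 98.5%, with 7 false calls. The simulation drew probe sets independently and with equal spread in both groups. The real arrays had 1 component with 79% of the variance, so these rates do not carry over to them.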

Results

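Transcripts of the mouse host were measured in tumours that human U87-EV glioblastoma cells had formed under the skin of SCID mice, which lack functional T and B cells. Total RNA of whole tumours, host stroma included, was hybridised to a mouse genome array of 45101 probe sets. The arrays came from 3 tumours of mice given saline and 3 tumours of mice given bevacizumab, an antibody against human VEGF-A, at 10 mg/kg every 3 days. Treatment had begun at a tumour volume of 150 to 200 mm3 and ended at a diameter of about 15 to 30 mm. The comparison asks how the host part of the tumour differed after the antibody. Of all probe sets, 14594 had a mean log2 value of at least 4 over the 6 arrays and were tested. The number of arrays limits the precision, and because the labels number the samples without stating that each came from its own animal, p-values measure the spread between these samples. Human transcripts can also bind to mouse probes, and the share of such signal in each value is unknown.

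The control arrays were not alike. Control replicates 1 and 2 held high levels of transcripts of blood-forming cells that lay far lower in control replicate 3 and in the treated arrays. Slc4a1, the anion exchanger of red cells, measured 13.23 and 12.87 log2 units in control replicates 1 and 2 and between 4.68 and 4.87 in the other 4 arrays. Alas2, the enzyme that starts haem synthesis in red cell precursors, measured 11.54 and 12.05 there against 3.95 to 5.74 elsewhere. Lists of red cell precursor, granulocyte precursor and megakaryocyte genes, drawn up after this had been seen, gave the same division, with 13 of 14, 8 of 9 and 8 of 10 measured genes at least 1 log2 unit above all 4 other arrays. The first principal component, with 79% of the variance, set control replicates 1 and 2 at -102.8 and -108.3 and the other arrays between 48.69 and 60.52. Hybridisation spike-ins averaged 10.5 and 10.6 log2 units on those 2 arrays and between 11.6 and 11.9 on the others. Values against control replicate 3 alone, a comparison added after the data had been seen, are therefore given for the lists and named genes below where the log2 value or the fold differs by over 1.5 times or a call ends.

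**Figure D1:**
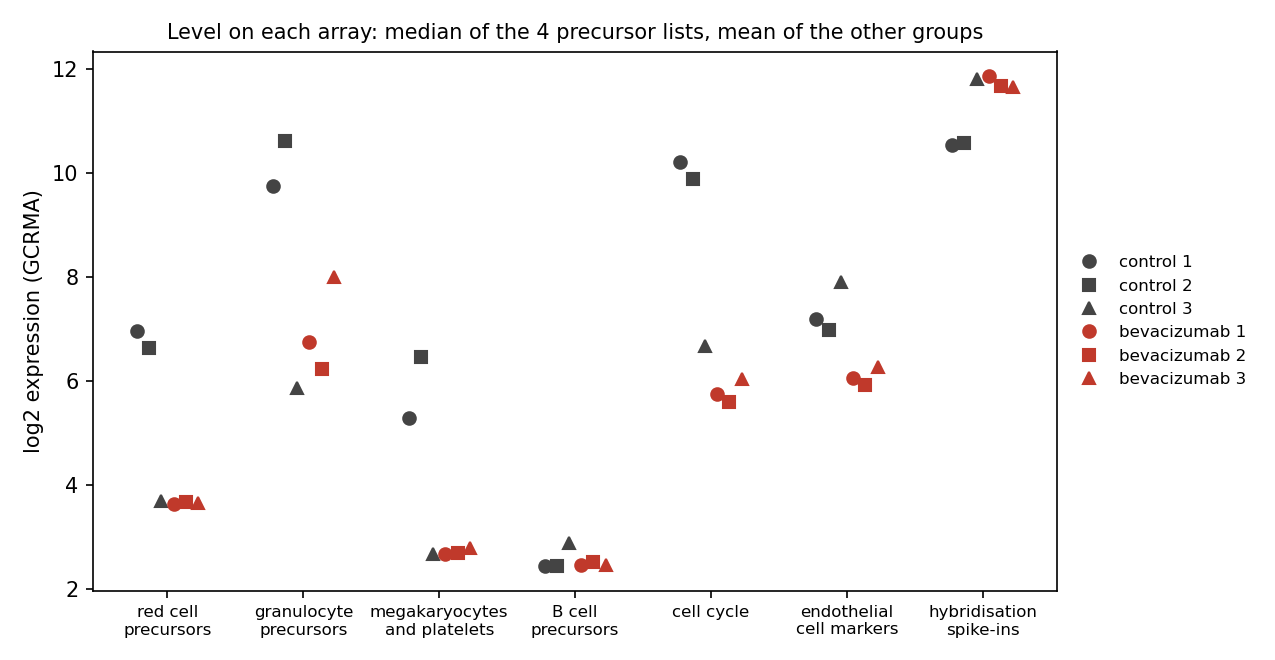
Log2 expression (vertical axis) on each of the 6 arrays for 4 precursor lists (median over the list), for the cell cycle and endothelial lists and for the hybridisation spike-ins (means). Control replicates 1 and 2 lie above all other arrays in the red cell, granulocyte and megakaryocyte lists and in the cell cycle list, and below them in the spike-ins.

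Across single genes, the treated tumours held more Arg1, the arginase of alternatively activated macrophages, and less Npnt, a matrix protein of basement membranes, and Gpihbp1, which holds lipoprotein lipase on capillary endothelium. No probe set passed an adjusted p of 0.05 with limma, and the lowest adjusted p was 0.0799, so the following are the genes with the lowest unadjusted p among those whose groups did not overlap, and all of them missed the threshold. Arg1 averaged 9.61 ± 0.0872 log2 units in the treated and 3.94 ± 1.26 in the control tumours (SD, n = 3 each), a difference of 5.67 ± 0.63 (SE) or 50.9-fold, and 20.7-fold against control replicate 3 alone. The highest ranks also held Pcsk5, a proprotein convertase, at 2.72 ± 0.21 log2 units above control, the transcription factor Jun at 1.99 ± 0.17, and the lactate exporter Slc16a3 at 2.37 ± 0.25. Ccr2, the chemokine receptor of inflammatory monocytes, was 1.54 ± 0.17 above control, and the serine protease Htra3 2.41 ± 0.26. Ptgfrn (2.52), Gpr171 (2.03), Cd209b (1.68) and Ahnak (1.62) completed the 10 with higher values.

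Among the genes with lower values, Npnt averaged 2.95 ± 0.135 in the treated and 7.39 ± 0.524 in the control tumours (SD, n = 3 each), a difference of -4.44 ± 0.29 log2 units (SE), and -3.84 against control replicate 3 alone. Gpihbp1 was at least 20.8-fold lower, and at least 41.1-fold against control replicate 3 alone, since the 3 treated values lay within 0.02 log2 units of one another at 4.72, the floor of this probe set. Icam2, an adhesion molecule of endothelium, differed by -2.20 ± 0.31 and Tmem204, a membrane protein of endothelial junctions, by -2.50 ± 0.20. Cep55, which acts in the last step of cell division, differed by -3.94 ± 0.46, and by -2.90 against control replicate 3 alone. The guidance molecule Sema6d (-2.51), the nuclear importer Ipo11 (-2.04), Tsc22d1 (-1.35), Zeb1 (-1.25) and Septin11 (-1.22) filled the remaining ranks. Another tested probe set of Zeb1 had the opposite sign.

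At an unadjusted p under 0.05 there were 2791 probe sets, 1115 higher and 1676 lower in treated tumours, against 730 expected by chance, and at an adjusted p under 0.1 there were 40. The count of 2791 was 1164 without control replicate 1, 1281 without control replicate 2, 1365 to 1442 without 1 treated array, 8000 without control replicate 3 and 8823 with array weights. Without a filter it was 2387, against 2252 expected by chance. The plain two-sample test, adjusted in the same way, also called 0. The groups did not overlap in 22.5% of the tested probe sets, where chance gives 10%. The share of higher values among those at an unadjusted p under 0.05 was 39.9% as deposited and 50.6% after quantile normalization, which moved the median difference over all genes from -0.14 to 0.15 log2 units. It was 50.1% to 58.8% when any 1 array other than control replicate 3 was left out, 58.9% against control replicate 3 alone and 49.6% without a filter, but 27.2% without control replicate 3 and 29.2% with array weights. The count at adjusted p was 6948 without control replicate 3, which leaves the 2 arrays with blood-forming transcripts as controls, and 2 against control replicate 3 alone.

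**Figure D2:**
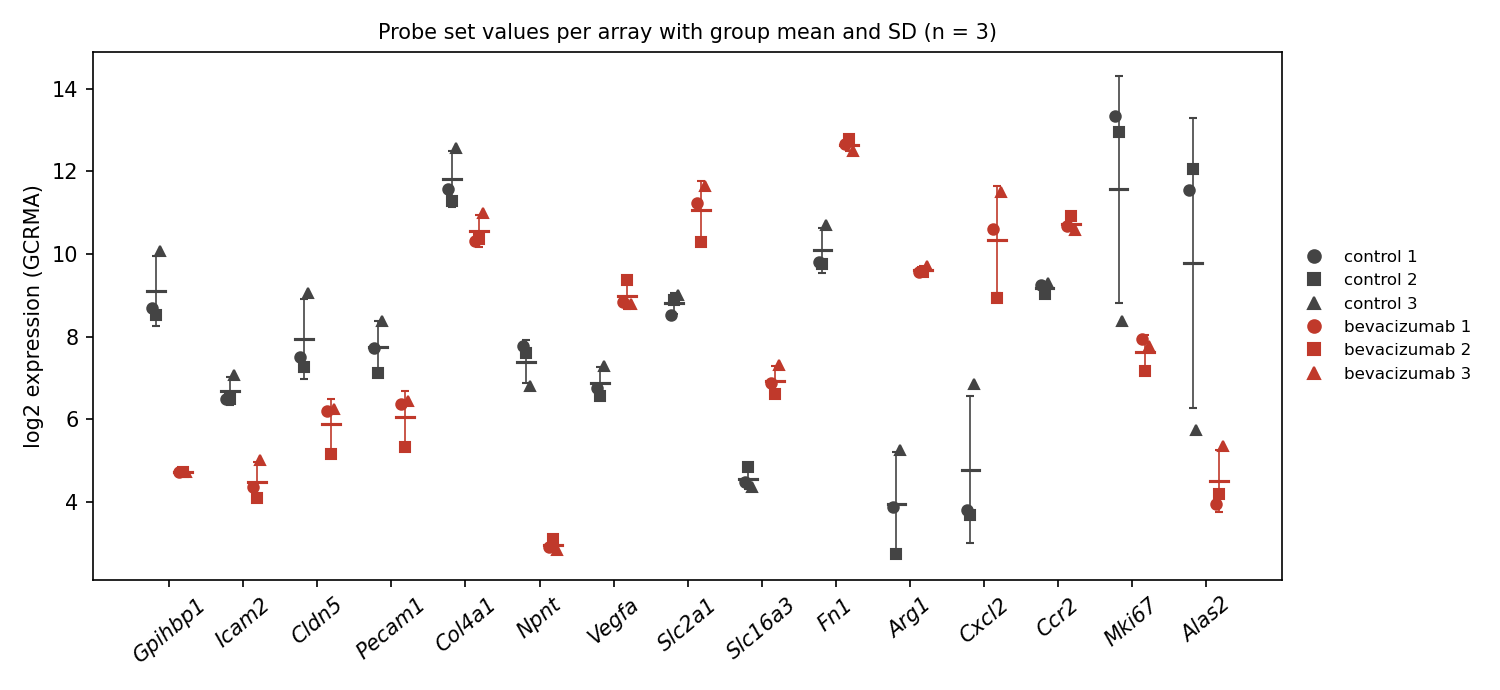
Log2 expression (vertical axis) of 15 genes on each array, control in grey and bevacizumab in red, with the group mean as a bar and the SD as a whisker (n = 3). Arg1 lies above 9.5 on all treated arrays and below 5.3 on all control arrays, while Mki67 and Alas2 are far higher on control replicates 1 and 2 than on the other arrays.

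Endothelial markers fell as a group. All 30 measured members of the endothelial list had lower values in the treated tumours, with a median difference of -1.02 log2 units (camera adjusted p = 1.22e-07, and adjusted p = 0.416 with an estimated correlation). None passed over all probe sets, and 12 did when adjusted over the list alone. Cldn5, a tight junction protein of endothelium, differed by -2.08 ± 0.57 log2 units (SE), and by -3.19 against control replicate 3 alone, and Pecam1, the endothelial adhesion molecule CD31, by -1.70 ± 0.45 and -2.33. Cdh5, the cadherin of endothelial junctions, differed by -1.03 ± 0.48, and by -2.02 against control replicate 3 alone. The VEGF receptor Kdr differed by -0.74 ± 0.34, and Flt1, another VEGF receptor, was at least 2.02-fold lower with its treated values at their floor. Kdr was at -1.48 and Flt1 at least 4.23-fold lower against control replicate 3 alone. That array held the highest control values of Cdh5, Kdr and Flt1 (6.63, 5.59 and 7.30). Control replicates 1 and 2 lay nearer the treated means of 4.61, 4.12 and 5.22. They held 5.33 and 4.93 for Cdh5, 4.53 and 4.45 for Kdr, and 5.70 and 5.71 for Flt1. Treated Kdr values lay close together, between 4.10 and 4.13, so its difference may be a lower bound. Tal1, a transcription factor that blood-forming cells share with endothelium, differed by -3.06 ± 1.42 but by 0.25 against control replicate 3 alone. Against that array the median of the list was -1.78, and without it -0.82, with 26 of 30 lower (camera adjusted p = 0.0246). After quantile normalization 26 of 30 were lower with a median of -0.79, and with the median shift 26 of 30 with -0.72.

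Genes that VEGF induces in sprouting endothelium did not pass as a list, with 14 of 20 lower and a median of -0.44 (adjusted p = 0.22). Against control replicate 3 alone the median was -1.26, and without control replicate 2 it was -0.69 (camera adjusted p = 0.00442). Without control replicate 3 it was -0.10 (adjusted p = 0.525) and with array weights -0.14 (adjusted p = 0.819), both with the camera direction upward. The median was -0.22 without a filter, -0.09 with the filter at 6, -0.21 after quantile normalization and -0.13 with the median shift. Kcne3 differed by -3.48 ± 0.68 log2 units (SE), the tip cell product Esm1 by -2.27 ± 0.90, Trp53i11 by -1.74 ± 0.31 and Igfbp3 by -1.61 ± 0.61, while Angpt2, a ligand of the endothelial receptor Tek, differed by -0.55 ± 0.45. Against control replicate 3 alone Kcne3 was at -4.86, Esm1 at -3.77, Trp53i11 at -2.37, Igfbp3 at -2.73 and Angpt2 at -1.52. That array held the highest control value of each of these genes. Angpt2 measured 6.16 and 5.97 in control replicates 1 and 2, around the treated mean of 6.00. Its value of 6.16 recurred in bevacizumab replicates 2 and 3, so these values may be background, though control replicate 2 and bevacizumab replicate 1 lay lower. In control replicates 1 and 2 Igfbp3 measured 10.7 and 9.91 against a treated mean of 9.26, and Esm1 6.16 and 3.63 against 3.38. The basement membrane list fell, with 10 of 12 members lower and a median of -0.68 (adjusted p = 0.0349, and 0.648 as the adjusted p with an estimated correlation). Its collagen chains Col4a1 and Col4a2 differed by -1.25 ± 0.40 and -1.38 ± 0.38 (-2.01 and -2.15 against control replicate 3 alone), and 0 members passed when adjusted over the list alone. Its median was -1.42 against control replicate 3 alone and -0.40 without that array, where the call was lost (adjusted p = 0.907), as it was without bevacizumab replicate 1 (0.104) and after quantile normalization (median -0.40, adjusted p = 0.0941). It was also lost with the median shift (-0.37, adjusted p = 0.128), without a filter (-0.20, adjusted p = 0.209) and with array weights (adjusted p = 0.685).

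Pericyte and smooth muscle markers moved both ways, 5 higher and 5 lower, with a median of -0.01 that turned to 0.28 after quantile normalization and was 0.12 against control replicate 3 alone (adjusted p = 0.578 as deposited). Rgs5 and Pdgfrb, both pericyte markers, were 1.18 ± 0.42 and 0.94 ± 0.36 log2 units higher (SE), although another tested probe set of Rgs5 had the opposite sign, and the channel subunit Abcc9 was at -1.83 ± 0.51. Rgs5 was at 0.24, Pdgfrb at 1.61 and Abcc9 at -2.51 against control replicate 3 alone. Lymphatic markers likewise did not pass (3 of 6 higher, median 0.02, and 0.48 against control replicate 3 alone, adjusted p = 0.195), and 4 members, 3 higher and 1 lower, passed when adjusted over the list alone. Pdpn and Lyve1 were 2.27 ± 0.36 and 2.03 ± 0.31 above control, and Flt4, the receptor of VEGF-C, was at -1.36 ± 0.43, while Pdpn was at 1.60 against control replicate 3 alone. The Notch list rose (8 of 10 higher, median 0.54, adjusted p = 0.0399, and adjusted p = 0.343 with an estimated correlation), and 1 member passed when adjusted over the list alone. Its transcription factor Rbpj was 1.22 ± 0.23 higher and the receptor Notch4 was at -1.44 ± 0.40. Dll4 was at 0.45 ± 0.45 and Nrarp, a regulator of Notch signalling, at -1.10 ± 0.44, and they were at -0.52 and -2.03 against control replicate 3 alone. The Notch call was lost in 8 of 17 other settings, among them quantile normalization (adjusted p = 0.0755) and leaving out control replicate 1 (0.0892), bevacizumab replicate 1 (0.0786) or bevacizumab replicate 2 (0.0717), and the Notch median was 0.33 without control replicate 2 and 0.18 against control replicate 3 alone. It was 0.84 under both scalings, 0.35 with the mean over probe sets, and 0.23 without a filter, where the call was lost (adjusted p = 0.0585). Angiogenic ligands and inhibitors rose (12 of 20 higher, median 0.40, adjusted p = 0.0106, and adjusted p = 0.416 with an estimated correlation), with 2 past when adjusted over the list alone, and against control replicate 3 alone they did not pass (adjusted p = 0.81). Their median was 0.13 without bevacizumab replicate 3, 0.78 after quantile normalization, 0.70 with the median shift and 0.04 without a filter. The mouse probe set for Vegfa was 2.13 ± 0.28 log2 units higher (limma adjusted p = 0.105), and the share of human signal in it is unknown. Vegfc was at -1.04 ± 0.44, and at -1.95 against control replicate 3 alone.

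Genes induced by hypoxia rose. Of 26 measured, 23 were higher, with a median of 0.93 log2 units (adjusted p = 2.96e-09, and adjusted p = 0.343 with an estimated correlation), and 9 passed when adjusted over the list alone. The mitophagy receptor Bnip3 was 2.63 ± 0.42 log2 units (SE) above control and the glucose transporter Slc2a1 2.26 ± 0.39. Anln, a cell division gene in the same list, was at -2.88 ± 0.94, and at -0.69 against control replicate 3 alone. The glycolysis list rose by a median of 0.39, with 14 of 18 higher and 4 past when adjusted over the list alone (adjusted p = 0.000306, and adjusted p = 0.427 with an estimated correlation). Hexokinase 2 (Hk2) was 1.55 ± 0.25 above control and the phosphofructokinase Pfkl 1.66 ± 0.43, while the lactate transporter Slc16a1 was at -2.45 ± 1.89. Pfkl was at 2.39 and Slc16a1 at 1.97 against control replicate 3 alone. The median of this list was 1.34 against control replicate 3 alone, 0.65 without control replicate 2, 0.66 after quantile normalization, 0.70 with the median shift and 0.25 without bevacizumab replicate 3, and without control replicate 3 it was 0.25 and the call was lost (adjusted p = 0.0701). Genes of fatty acid uptake and lipid storage rose by a median of 0.28 (13 of 16 higher, 1 past when adjusted over the list alone, adjusted p = 0.00857, and adjusted p = 0.427 with an estimated correlation). Hilpda, a lipid droplet protein, was 2.80 ± 0.82 above control and 1.82 above control replicate 3. Cd36, a fatty acid transporter, was at -1.30 ± 1.22, and at 1.36 against control replicate 3 alone. The lipid storage median was 1.18 against control replicate 3 alone, 0.43 without control replicate 1, 0.56 without control replicate 2 and 0.47 without bevacizumab replicate 1, and 0.62 and 0.58 under the 2 scalings. Without control replicate 3 it was 0.09 and the call was lost (adjusted p = 0.144), as it was with array weights (0.05, adjusted p = 0.126).

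Interstitial matrix genes rose. In the fibroblast and interstitial matrix list 26 of 29 members were higher, with a median of 1.11 log2 units (adjusted p = 1.74e-10, and adjusted p = 0.343 with an estimated correlation), and 11 passed when adjusted over the list alone. Fibronectin (Fn1) was 2.56 ± 0.30 log2 units (SE) above control, tenascin C (Tnc) 3.20 ± 0.68, fibulin 2 (Fbln2) 2.39 ± 0.52 and dermatopontin (Dpt) 2.09 ± 0.68. Fn1 was at 1.94, Tnc at 2.12 and Dpt at 3.40 against control replicate 3 alone. Matrix proteases and their inhibitors rose by a median of 0.94, with 11 of 17 higher and 6 past when adjusted over the list alone (adjusted p = 0.000194, and adjusted p = 0.416 with an estimated correlation). The collagenase Mmp13 was 3.55 ± 0.84 above control, Mmp11 2.13 ± 0.41, Mmp3 2.03 ± 0.33 and the gelatinase Mmp2 1.89 ± 0.37. Against control replicate 3 alone the protease median was 0.53, Mmp13 was at 2.38, Mmp11 was at 1.255 and Mmp2 at 1.16, and the list did not pass (adjusted p = 0.317). Adipocyte markers rose by a median of 1.43 (11 of 12 higher, 0 past when adjusted over the list alone, adjusted p = 0.000208, and adjusted p = 0.416 with an estimated correlation), with Fabp4, the fatty acid binding protein of fat cells, 1.47 ± 0.60 above control and Plin4, a lipid droplet coat protein, 1.83 ± 0.52. Fabp4 was at 2.43 against control replicate 3 alone, and Cd36 belongs to this list too. The adipocyte median was 0.69 without control replicate 3, 0.92 without bevacizumab replicate 2, 0.63 without a filter and 0.67 with array weights.

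Macrophage markers and inflammatory mediators rose. Of 30 macrophage markers 29 were higher, with a median of 0.79 log2 units (adjusted p = 1.64e-13, and adjusted p = 0.343 with an estimated correlation), and 15 passed when adjusted over the list alone. Beside Arg1 and Ccr2, the scavenger receptor Msr1 was 2.21 ± 0.54 log2 units (SE) above control, the folate receptor Folr2 2.24 ± 0.46, and the lysosomal marker Cd68 0.84 ± 0.26. Against control replicate 3 alone Msr1 was at 1.08, Folr2 at 1.31 and Cd68 at 0.51. All 15 inflammatory cytokine and chemokine genes were higher, with a median of 1.68 (adjusted p = 1.74e-10, and adjusted p = 0.343 with an estimated correlation), and 11 passed when adjusted over the list alone. The neutrophil chemoattractant Cxcl2 was 5.57 ± 1.09 above control, the prostaglandin synthase Ptgs2 4.32 ± 0.74 and the chemokine Ccl3 3.80 ± 0.73. Ccl3 held the same value of 2.58 in control replicates 1 and 2, as at a floor, so its difference is a lower bound. The inflammatory median against control replicate 3 alone was 1.06, with Cxcl2 at 3.50 and Ccl3 at 2.76. Genes of dendritic cells and MHC class II rose by a median of 0.60 (6 of 6 higher, 0 past when adjusted over the list alone, adjusted p = 0.00337, and adjusted p = 0.352 with an estimated correlation), with the invariant chain Cd74 0.70 ± 0.23 above control, and did not pass against control replicate 3 alone (adjusted p = 0.304). Their median was 0.15 without a filter and 0.91 with the median shift.

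Neutrophil markers did not pass (8 of 17 higher, adjusted p = 0.578), and their median of -0.35 had the opposite sign to the camera direction. The median was 1.06 against control replicate 3 alone (adjusted p = 0.083) and -0.97 without control replicate 3. Their secondary granule genes followed the blood-forming transcripts of control replicates 1 and 2. Ngp was at -3.93 ± 1.91 log2 units (SE) and Ltf at -3.33 ± 2.03, and against control replicate 3 alone they were at 0.18 and 1.33. S100a8, which mature neutrophils also hold, was at -0.35 ± 0.70, and at 0.89 against control replicate 3 alone. Without bevacizumab replicate 2 the neutrophil median was 0.18 and the list passed (adjusted p = 0.0245). NK cell and lymphocyte markers did not pass (3 of 6 higher, median 0.04, and 0.15 against control replicate 3 alone, adjusted p = 0.651).

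Cell cycle genes fell by a median of -3.33 log2 units, with 23 of 24 lower and 17 past when adjusted over the list alone (adjusted p = 1.78e-07, and adjusted p = 0.416 with an estimated correlation). This list too followed control replicates 1 and 2, whose mean levels were 10.2 and 9.88 log2 units against 6.66 in control replicate 3 and 5.59 to 6.03 in the treated tumours. Against control replicate 3 alone the median was -0.88, and 19 of 24 genes had all treated values below that array. The proliferation marker Mki67 differed by -3.94 ± 1.36 (SE), and by -0.76 against control replicate 3 alone, and the spindle protein Nusap1 by -4.94 ± 1.33 and -2.19. Ribosomal protein genes fell by a median of -0.38 (27 of 29 lower, 0 past when adjusted over the list alone, adjusted p = 0.00866, and adjusted p = 0.606 with an estimated correlation), with Rps25 at -1.40 ± 0.57 and Rpl37 at 1.45 ± 0.67, and at -0.25 and -0.031 against control replicate 3 alone. Control replicates 1 and 2 averaged 12.7 log2 units in this list and the other arrays between 12.03 and 12.1, and the call was lost against control replicate 3 alone (median 0.00074, adjusted p = 0.52) and with each array shifted to the same median (-0.08, adjusted p = 0.097). The ribosomal median was -0.23 without control replicate 1, -0.59 without control replicate 3, -0.12 after quantile normalization and -0.61 with array weights.

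Immediate early and heat shock genes, which can respond to the handling of tissue, rose by a median of 0.61 (11 of 16 higher, 7 past when adjusted over the list alone, adjusted p = 0.000457, and adjusted p = 0.343 with an estimated correlation). Atf3 and Ier3, both stress-response genes, were 2.76 ± 0.53 and 2.20 ± 0.33 log2 units (SE) above control, while the heat shock protein Hsph1 was at -1.91 ± 1.01, and at 0.33 against control replicate 3 alone. Against that array the list did not pass (adjusted p = 0.0544). Its median was 0.17 without control replicate 1. Transcripts abundant in cultured glioma cells, as read by the mouse probes, rose by a median of 0.51 (14 of 21 higher, 0 past when adjusted over the list alone, adjusted p = 0.00274, and adjusted p = 0.343 with an estimated correlation), with the calcium-binding protein S100a4 1.22 ± 0.56 and the galectin Lgals3 1.02 ± 0.51 above control and the annexin Anxa1 at -1.85 ± 1.03. The list did not pass against control replicate 3 alone (median 0.18, adjusted p = 0.248), where S100a4 was at 2.33, Lgals3 at 1.99 and Anxa1 at 0.51. Its median was 0.81 with the median shift, 0.31 with array weights and 0.21 without the probe sets that can match several genes. Genes of the unfolded protein response (6 of 15 higher, median -0.31, adjusted p = 0.93), interferon-stimulated genes (10 of 20 higher, median 0.01, adjusted p = 0.301) and Schwann cell markers (4 of 5 higher, median 0.19, adjusted p = 0.274) did not pass. These medians were 0.29, 0.16 and 0.12 against control replicate 3 alone, and without it the unfolded protein response median was -0.67. The interferon list passed without bevacizumab replicate 2 (median 0.28, adjusted p = 0.0468), and its median was -0.26 without bevacizumab replicate 3. Over all settings the medians of lists that missed the threshold ranged from -0.26 to 0.34 (interferon), -0.67 to 0.29 (unfolded protein response), 0.04 to 0.50 (Schwann), -0.18 to 0.29 (pericyte), -0.21 to 0.48 (lymphatic), -0.16 to 0.34 (NK cell and lymphocyte) and -0.97 to 1.06 (neutrophil). Mast cell, skeletal muscle, skin and red blood cell lists had 2, 3, 1 and 4 measured genes, fewer than the 5 a test required. In all, 17 of 25 tested lists passed, 13 higher and 4 lower, and with an estimated correlation 0 did. Among those 17 the estimated correlation ran from -0.0725 (Notch) to 0.837 (basement membrane). Unadjusted fry p was 0.155 (adipocyte), 0.233 (glycolysis), 0.243 (lipid storage), 0.207 (basement membrane), 0.113 (angiogenic), 0.119 (ribosomal), 0.0989 (protease) and 0.0584 (glioma-abundant). It was under 0.05 for the other called lists, and for the lymphatic list (0.00509), which camera did not call.

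**Figure D3:**
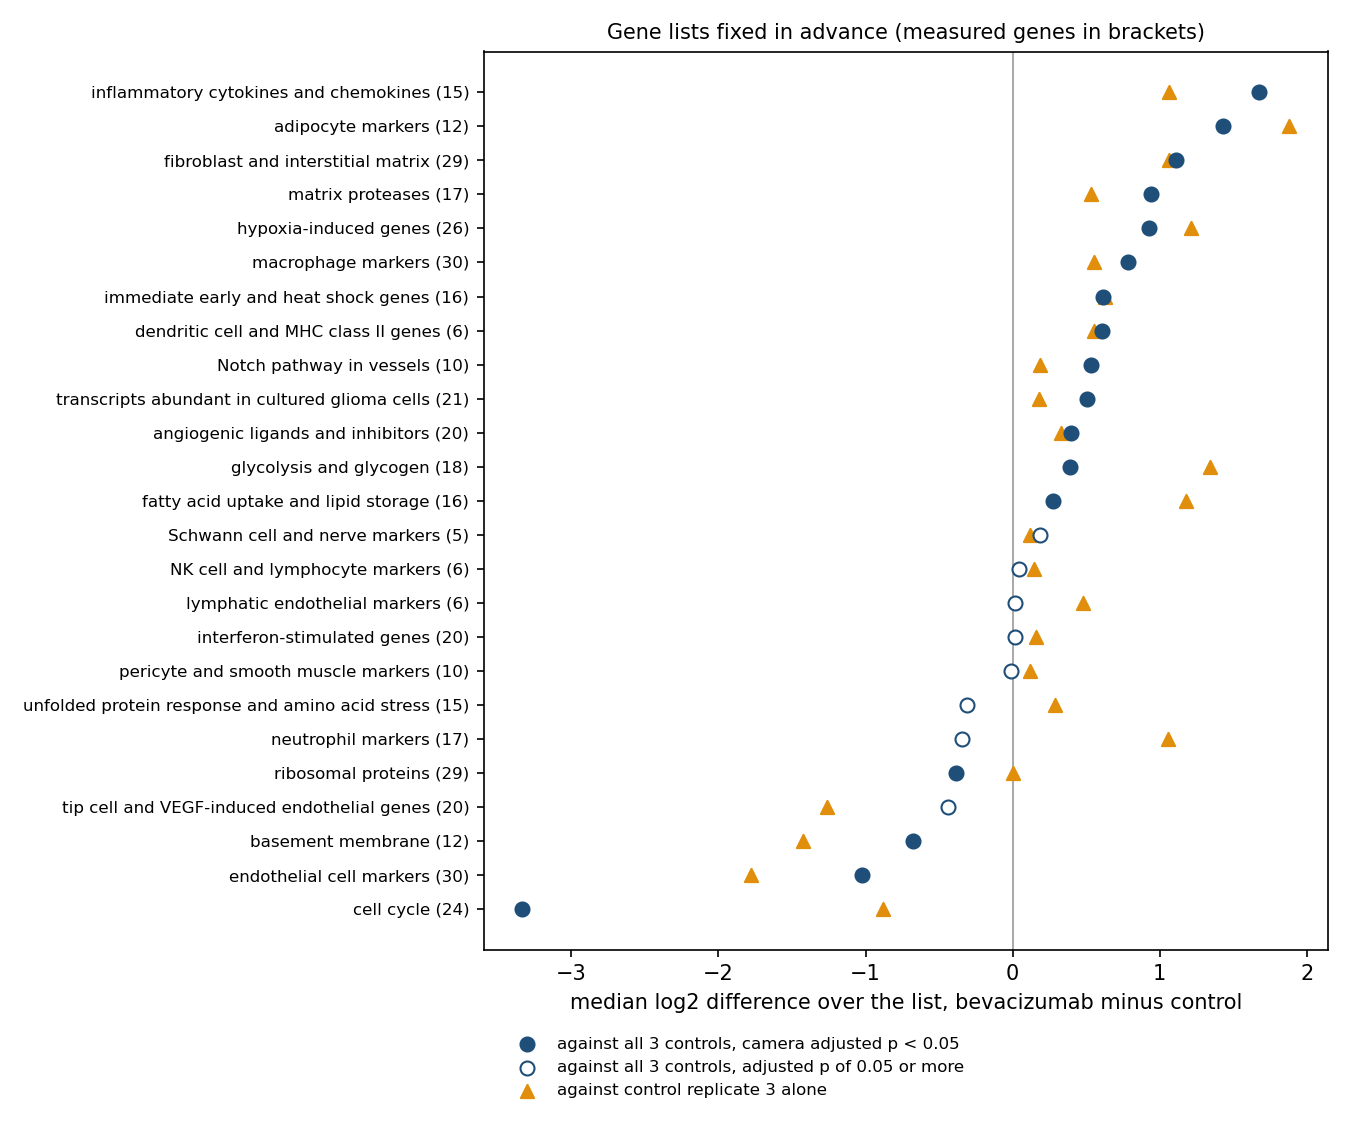
Median log2 difference, bevacizumab minus control (horizontal axis), of the 25 tested gene lists, against all 3 control arrays (circles, filled where the camera adjusted p was under 0.05) and against control replicate 3 alone (triangles). The endothelial list lies at -1.02 and -1.78, and the cell cycle list at -3.33 and -0.88.

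RNA integrity was read from control probe sets at both ends of 2 transcripts. The 3 prime to 5 prime difference of Gapdh was -0.47 ± 0.179 log2 units in control and -0.39 ± 0.0598 in treated tumours (SD, n = 3 each, exact permutation test, two-sided, p = 0.7). For beta-actin (Actb) it was 1.03 ± 0.0391 and 1.26 ± 0.0667 (SD, n = 3 each, exact permutation test, two-sided, p = 0.1, the smallest p that 3 against 3 arrays allow).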

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

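The control probe sets of the array lay outside the comparison. In 1 of 7 classes of them, those for mouse pyruvate carboxylase, every treated array lay above every control array, with a mean difference of 0.0683 log2 units. The values were 3.14, 3.14 and 3.03 in the control and 3.15, 3.21 and 3.15 in the treated tumours, near the floor.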

How the results depend on the processing

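The comparison without control replicates 1 and 2 was chosen after the data had been seen. Arrays in each group and the distance of a signal from its floor limit what can be read. A 2-fold minimum could only lower the count of probe sets at an adjusted p under 0.05, so its outcome of 0 was fixed. The count of 0 also held without a filter, with the filter at 6, with trend and robust settings and with the plain test. It was 3 after quantile normalization and 3 with the median shift (1 higher and 2 lower each), 8011 with array weights (2215 higher, 5796 lower), 2 without control replicates 1 and 2, 40 at an adjusted p under 0.1 and 2791 at an unadjusted p under 0.05. The last count ranged from 1164 (without control replicate 1) to 8000 (without control replicate 3) when 1 array was left out, and was 2387 without a filter, where chance gives 2252. Leaving out 1 array gave 0 to 6948 (1744 higher and 5204 lower without control replicate 3). Array weights gave control replicate 3 a weight of 0.078, so both large counts rest on setting that array aside; the cause of the other changes was not tested. The median difference over all genes was -0.14 as deposited, 0.15 after quantile normalization and 0.17 after the median shift. Of the list calls, 17 became 11 without control replicates 1 and 2 (7 higher, 4 lower), 0 with an estimated correlation, and 14 to 18 when 1 array was left out. Of those 17, 7 were lost only with the estimated correlation and 10 in another camera setting too. The medians of all 17 kept their sign under both scalings, but 8 of them moved by over 1.5 times under at least 1 (basement membrane, Notch, angiogenic ligands, MHC class II, glycolysis, lipid storage, ribosomal and glioma-abundant genes). The endothelial median of -1.02 ranged from -0.82 to -1.29 when 1 array was left out, and missed the threshold only with the estimated correlation (median -1.02, adjusted p = 0.416). No pairing by replicate number showed, as deviations of same-numbered arrays from their group means correlated at -0.025, -0.181 and -0.13. The control deviations carried the division of control replicates 1 and 2 from 3, so this check could not exclude a pairing. A fit with the replicate block gave 0 probe sets and 17 lists.

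Of the 130 named genes, 104 kept their sign in every limma fit that held them, and Mylpf in all but the 2 scalings. Without control replicates 1 and 2 the log2 difference changed sign to -0.52 for Dll4, 0.89 for S100a8, 0.25 for Tal1, 0.11 for Tagln, 0.13 for Stab2, 0.95 for Camp, 0.18 for Ngp, 1.33 for Ltf, 0.62 for Lcn2, 0.39 for Gzma, 0.11 for Kit, 0.12 for Cnp, -0.44 for Sox10, -0.41 for Egfl8, 1.97 for Slc16a1, 1.36 for Cd36, 0.08 for Igtp, 1.25 for Rsad2, 0.56 for Ppp1r15a, 0.33 for Hsph1, -0.031 for Rpl37, 0.0011 for Rpl14, 0.029 for Rps6 and 0.51 for Anxa1. When 1 array was left out, S100a8 ranged from -0.97 (without control replicate 3) to 0.17 (without bevacizumab replicate 2), Hdc from -0.43 (without control replicate 3; -0.10 without bevacizumab replicate 3) to 0.98 (without bevacizumab replicate 2), and Sox10 from -0.031 (without control replicate 1) to 0.75 (without control replicate 3). Hdc was at -0.15 with array weights. Kit was at 0.050 with the median shift, and Mylpf at 0.040 after quantile normalization and 0.14 with the median shift. That shift moves every gene of an array alike and all treated values of Mylpf lay at its floor, so its sign there carries no information on the gene. For RNA integrity, the Gapdh difference between groups was 0.08 with 5 prime probe sets and -0.161 with middle ones, and the Actb difference was 0.225 (exact permutation p = 0.1) and 0.00829 (p = 0.9). The cause was not tested.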

Other observations

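All tests of explanations below were chosen after the results had been seen, and the use of quartiles after the quartiles themselves. Ranked by the distance between the nearest treated and control arrays, several genes outside the lists fixed in advance stood apart, and all missed an adjusted p of 0.05 with limma. Hcar2, a receptor for hydroxycarboxylic acids on myeloid and fat cells, was 4.89 log2 units higher in treated tumours, and 28.4-fold higher against control replicate 3 alone. The B cell chemoattractant Cxcl13, which the later spleen list holds, was 3.71 higher (4.69 against control replicate 3 alone). The mucin-like protein Glycam1 was 4.69 higher (5.70) and Acod1, the itaconate-producing enzyme of activated macrophages, 3.88. Glycam1 measured 2.35 and 2.34 in control replicates 1 and 3, near the lowest value of 2.32, so its differences are lower bounds. Among lower genes, the imprinted gene Mest was at -3.28 (-4.10), Gimap4 at -2.25 (-2.86) and Ramp3, a receptor partner found on endothelium, at -2.39, and at -4.14 against control replicate 3 alone.

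Control replicates 1 and 2 stood apart from control replicate 3 and held transcripts of blood-forming cells. A larger share of mouse RNA of every kind cannot be judged from these values, which are relative within each array. On these arrays 27 of 30 endothelial genes were lower than in control replicate 3. The hybridisation spike-ins were lower there too, at 10.5 and 10.6 against 11.8 log2 units. The values show only that endothelial and blood-forming transcripts moved in opposite directions. Whether control replicate 3 is a treated tumour under a wrong label cannot be settled from 1 array. It lay above all 3 treated arrays in 28 of 30 endothelial genes, but that these genes mark treatment rests partly on this array. Over the tested probe sets it correlated at 0.9485 to 0.9585 with treated arrays and at 0.8357 and 0.8186 with control replicates 1 and 2. Treated arrays correlated with one another at 0.9714 to 0.9807. RNA of mouse blood-forming tissue in these samples is a candidate explanation, since the lowest of the median gaps of the 3 precursor lists was 1.82 log2 units (3.37 in red cell, 1.82 in granulocyte and 1.88 in megakaryocyte genes; 1 of 14, 4 of 9 and 1 of 10 genes also belong to the first lists). Its origin and a separate labelling batch stay open. Among the spleen genes 3 of 11 (Stab2, Cd5l and Treml4) had a gap over 1. That count lies between the outcomes set for spleen RNA and for its absence, so it argues neither way. The B cell precursor, bone and liver lists had gaps of -0.091, -0.148 and -0.0249 with 0 genes over 1. How many B cell precursors these SCID mice held is not given, so the low B cell precursor genes do not decide the origin. The spike-ins lay 1.08 log2 units apart with no batch in the labels.

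Endothelial markers were lower in the treated tumours. Whether they held a smaller share of mouse host RNA cannot be told from values that are relative within each array. The macrophage median was 0.7876 log2 units above control, and 0.5504 against control replicate 3 alone. Host transcripts therefore did not all fall alike, but 1 cell type cannot report the total share. Blood-forming RNA in control replicates 1 and 2 as the whole cause is argued against, because 27 of 30 endothelial genes were lower there than in control replicate 3 (median -1.05, quartiles -1.43 and -0.739 log2 units). Without those arrays the list median was -1.78, against 1 control array. The antibody itself, which the design names, stays open as untested beyond this comparison.

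Hypoxia-induced genes were higher in the treated tumours. Blood-forming RNA in control replicates 1 and 2 would have to lower these genes there, but 18 of 26 were higher than in control replicate 3 (median 0.234 log2 units), and without those arrays the list median was 1.215. This argues in the other direction without settling it, since the quartiles of -0.268 and 1.34 span 0 and 1 control array remains. Human tumour transcripts binding to mouse probes may also contribute. The list abundant in cultured glioma cells had a median of 0.505, which does not decide it. The values do not show which probe sets respond to human sequence. The antibody stays open as untested beyond this comparison.

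The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. At adjusted p all 10 splits gave 0 probe sets, the highest other being 0. At an unadjusted p under 0.05 the real split gave 2791 and the highest other 2245, from control replicates 1 and 2 with bevacizumab replicate 3. Only the real split reached that count. For gene lists the real split gave 17 and the highest other 14. For the endothelial median the real value was -1.02 and the highest other 0.811 in size. Only the real split reached either value. Splits other than the real one called 7 to 14 lists at the preset correlation. Each of them still holds unequal numbers of treated and control arrays per side, so treatment and other structure of the samples cannot be told apart there.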
